A study of Mus musculus with 6 samples.

How the data were processed

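RNA from bone marrow of leukaemic NUP98/HOXD13 mice was measured on Affymetrix MG-430_2.0 arrays, with 3 samples labelled Gfi1b KO and 3 labelled wildtype. Per the labels, 200 ng of total RNA was converted to biotinylated cRNA with the Express Kit protocol, fragmented and hybridised. The deposited values are on the log2 scale and come from RMA, per the submitters' processing notes, which corrects background, normalizes the arrays by quantiles and summarises the probes of each probe set. The version of RMA is not given in the sources used here, and scanner files were not used here. RMA brings all arrays to nearly the same distribution, so differences are relative to the other genes of an array, and very low genes are compressed at a floor. A second deposited table holds the same log2 values, gene symbols, the authors' signed fold changes and log2 differences, and the authors' unadjusted and adjusted p-values for KO against wildtype and for an ANOVA. The largest difference between the group means of the 2 deposited tables was 0. The unadjusted p-values of the authors' KO against wildtype column differ from a limma fit over all probe sets by at most 4.95e-08.

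Gene symbols were taken from the deposited annotated table. Of 45101 probe sets, 64 are array controls, 37285 name 1 gene, 1796 name several and 5956 name none. Probe sets naming 1 gene were kept, and a gene was represented by its probe set with the highest mean over the 6 samples, which left 20577 genes. Of 20724 distinct symbols, 15159 are current symbols of RefSeq genes (GRCm38.p6) and 2676 are synonyms that were updated, and 2889 kept the name of the file. No genome build is named in the files, and no coordinates are given. Of 60 named genes past the threshold, 33 had further probe sets, 64 in all. Of these further probe sets, 59 had the same sign, 27 were also past the threshold in the same direction and 0 in the other.

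Genes were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), KO minus wildtype, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. There was no filter on dim genes and no further normalization. Gfi1b was also tested with an exact permutation test. The 28 tested gene lists were fixed before the data were examined from textbook knowledge of marrow cell types, leukaemia and Gfi1b. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists, and again with an estimated correlation and with fry. Some genes stand in several lists (Btg2, Dusp1, Csf1r and Gata2 among them). The rule for named genes was also fixed before the data were examined. It takes Gfi1b and Gfi1, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap, the 4 members with the smallest p-value in the direction of each list past camera and 2 of each other list, a fixed set of 14 genes including Foxo1, Kit, Hoxa9 and Gata1, and the sex-linked genes. Symbols without a proper name and receptor segments were left out of the largest changes, and 81 genes past the threshold had such symbols. The bright adult globin probe sets name several genes and therefore do not enter the erythroid list, whose only adult globin member is Hba-a1, at a probe set near the floor (log2 fold change -0.09). Some genes that the rule takes are not reported here. Any further gene named is said to have been chosen after its value was seen. Standard deviations and n are over samples, and an error given for a fold change is limma's standard error.

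The gene and list tests were tested on simulated data, with 200 of the 20577 genes changed in a 3 against 3 comparison. Of the 50 genes changed by 1 on the log2 scale 44% were recovered, of those changed by 2, 4 and 6 the shares were 80%, 96% and 100%, and 4.76% of the 168 calls were false. The shifted list was recovered and 0 of 27 other lists passed. These simulated samples vary independently between genes, which the correlated genes of real marrow do not.

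The alternatives fixed before the data were examined were a replicate block, each sample left out in turn, a repeated quantile normalization, the values of the annotated table, an intensity trend, array weights, robust moderation, no moderation, filters on dim genes, the mean of all probe sets of a gene, all probe sets, other thresholds, the authors' statistics, and other list tests. Leaving out probe sets that can cross-hybridise was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.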

Results

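Gene expression was measured in bone marrow of leukaemic mice that carry a NUP98/HOXD13 transgene, a fusion of a nucleoporin gene with a homeobox gene that is used to model myelodysplastic syndrome and acute myeloid leukaemia. All 6 genotypes named in the labels carry Mx-Cre, an inducible recombinase. The labels place 3 samples in a group with floxed Gfi1b alleles, called Gfi1b KO, and 3 in a group with wildtype Gfi1b. Gfi1b encodes a transcriptional repressor of the erythroid and megakaryocytic lineages and of blood stem cells. The comparison asks how marrow that became leukaemic differs between the 2 Gfi1b genotypes. Each sample was hybridised to its own array of 45101 probe sets, and the number of arrays limits the precision. The labels do not state that the samples of a group came from separate mice, so the p-values measure the spread between these samples. The sex-linked genes, given below, show only that the samples labelled KO did not all come from the same mouse. The array medians lay between 3.73 and 3.86 on the log2 scale. Pearson correlations across probe sets lay between 0.949 and 0.972 within the KO group, between 0.947 and 0.970 within the wildtype group, and between 0.860 and 0.933 across the groups. The first principal component held 63.2% of the variance and separated the groups.

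The targeted gene itself was higher, not lower, in the samples labelled KO. Gfi1b read 10.88, 11.63 and 11.67 on the log2 scale in KO replicates 1, 2 and 3, and 5.83, 6.37 and 4.38 in wildtype replicates 1, 2 and 3. The group means were 11.39 ± 0.45 (SD, n = 3) and 5.53 ± 1.03 (SD, n = 3), a 58.2-fold difference. The log2 fold change was 5.86 with a standard error of 0.51 in limma over all probe sets (adjusted p = 0.00714), and the adjusted p was 0.00605 over genes. An exact two-sided permutation test of 3 against 3 samples gave p = 0.1, the smallest value it allows. Only 1 probe set named Gfi1b. The labels do not say which exons were deleted, and a probe set outside the deleted part cannot check the labels. The direction is not that of a lost transcript, but with the deleted part unknown it does not decide whether the labels are right. Every direction given here is that of the samples labelled KO. Gfi1, the paralog of Gfi1b that acts in granulocytes and lymphocytes, read 6.40 ± 1.02 in the samples labelled KO and 5.68 ± 0.45 in wildtype (SD, n = 3), and its limma adjusted p of 0.53 did not pass.

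Expression differed widely between the groups, with granule and lysozyme genes at one end and F2r, Dsp and Car1 at the other. Lyz2, a lysozyme of myeloid cells, averaged 6.40 ± 2.22 in the samples labelled KO and 13.76 ± 0.68 in wildtype (SD, n = 3), 165-fold lower (limma adjusted p = 0.019). Mpo, the myeloperoxidase of granulocyte precursors, was 129-fold lower (adjusted p = 0.0164). F2r, the thrombin receptor, averaged 11.39 ± 0.24 against 5.18 ± 1.52 (SD, n = 3), 74.3-fold higher (adjusted p = 0.0112). Car1, a carbonic anhydrase of erythroid precursors, was 44.7-fold higher (adjusted p = 0.0292). Among 20577 genes, 933 passed an adjusted p under 0.05 in limma, 453 of them higher and 480 lower in the samples labelled KO. Of these, 361 rose and 430 fell by at least 1 on the log2 scale, and 51 rose and 140 fell by at least 3. At an unadjusted p under 0.05 there were 3961 genes, 2023 higher and 1938 lower. The groups did not overlap in 25.2% of all genes, where chance gives 10%. The authors' deposited table, which tests probe sets, lists 1320 past its adjusted p, 690 higher and 630 lower. The count of 933 was 395, 47 and 440 genes without KO replicate 1, 2 or 3, and 349, 1445 and 467 without wildtype replicate 1, 2 or 3. Without KO replicate 2 the 60 named genes past the threshold kept their direction, but 57 of them, Gfi1b, F2r, Mpo and Lyz2 among them, lost the call.

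**Figure D1:**
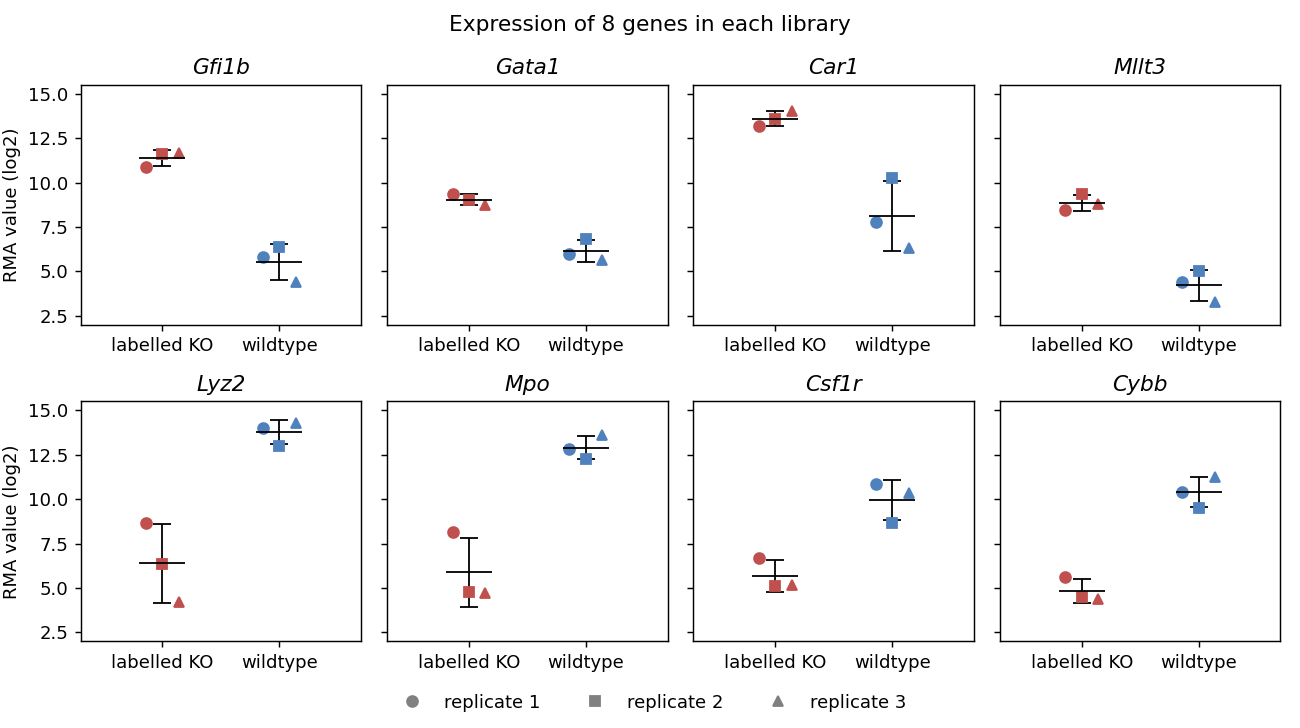
RMA values on the log2 scale of 8 genes in the 3 samples labelled KO (red) and the 3 wildtype samples (blue), with symbols for the replicates, and horizontal lines and bars for the mean and SD. Gfi1b, Gata1, Car1 and Mllt3 lie higher and Lyz2, Mpo, Csf1r and Cybb lower in every sample labelled KO than in every wildtype sample.

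The genes with the largest rises came from several functions. Besides F2r and Gfi1b, they included Car1 with a log2 fold change of 5.48 and Dsp, which encodes a desmosome protein, with 5.49. Clca1 changed by 5.34 and Rab4a, a GTPase of endosomal recycling, by 5.10. Gstm5, a glutathione transferase, rose by 5.05. Col5a1, a collagen chain, rose by 4.82, Grb10, an adaptor of receptor signalling, by 4.81, Cd59a, an inhibitor of complement, by 4.76, and Mllt3, a regulator of blood stem cells, by 4.65. In wildtype Dsp averaged 3.45 and Grb10 3.71, below the array medians and near the floor, so their changes are lower bounds and have no set order among the others. Nfe2l2, which encodes the antioxidant regulator NRF2, rose by 4.86 at the probe set that represents it. Its other probe set read 5.88 in the samples labelled KO and 7.00 in wildtype, and Nfe2l2 changed by -1.16 with an adjusted p of 0.536 after a further quantile normalization, when that probe set represented the gene. Clca1 likewise rests on a probe set that can cross-hybridise, and changed by 0.22 (adjusted p = 0.636) without such probe sets. The probe set that then represented Clca1 averaged 3.58 and 3.36 in the 2 groups, near the floor, and cannot check the rise. Mllt3 also rests on a probe set that can cross-hybridise. Its other probe sets rose by 1.99 (limma adjusted p over probe sets = 0.0474), or differed by 1.15 and 0.77 without passing. The latter averaged 3.84 and 3.21 in wildtype, near the floor. The 12 largest falls were those of lysozyme, granule and other leukocyte genes. Lyz2 fell by 7.36 and Lyz1 by 7.10 on the log2 scale. Every probe set of Lyz1, and every one of F2r above, is of the kind that can cross-hybridise. Their changes therefore could not be checked without such probe sets. The granule genes Ltf, Mpo, Camp, Lcn2, Pglyrp1 and Mmp8 fell by 7.02, 7.01, 6.95, 6.48, 6.46 and 6.39. Chil3, a secreted protein of myeloid cells, fell by 6.78, Cd52, a leukocyte surface antigen, by 6.53, F13a1, a coagulation factor of monocytes, by 6.52 and Stfa2l1, a stefin, by 6.26.

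Neutrophil, monocyte and oxidative burst genes fell together in the samples labelled KO. Of 28 measured neutrophil and granule genes, 21 fell, 0 rose and 7 did not pass over all genes, and 27 fell adjusted over the list alone. Their median log2 fold change was -5.64 (camera adjusted p = 2.84e-22, and adjusted p = 0.392 with an estimated correlation). Camp, Ltf, Pglyrp1 and the leukotriene B4 receptor gene Ltb4r1, which changed by -2.87, had the smallest p-values. Of 25 monocyte and macrophage genes, 9 fell and 0 rose, with 14 falling adjusted over the list alone and a median of -1.54 (camera adjusted p = 3.42e-08, and adjusted p = 0.573 with an estimated correlation). Irf8, a transcription factor of monocytes and dendritic cells, changed by -5.12, a lower bound in size with a mean of 3.80 near the floor in the samples labelled KO, Ly86 by -5.06 and the macrophage colony-stimulating factor receptor gene Csf1r by -4.30. Of 9 genes of the NADPH oxidase list, 6 fell over all genes and 7 adjusted over the list alone, with a median of -2.54 (camera adjusted p = 1.94e-07, and adjusted p = 0.392 with an estimated correlation). They included Cybb, the catalytic subunit of the phagocyte oxidase, with -5.56, and its cytosolic partners Ncf1 and Ncf4 with -4.80 and -4.50. Of 25 integrin and adhesion genes, 6 fell, 10 adjusted over the list alone, while 2 rose adjusted over the list alone (median -0.60, camera adjusted p = 0.0011, and adjusted p = 0.585 with an estimated correlation). Selplg, a selectin ligand of leukocytes, changed by -3.61, and the leukocyte integrin genes Itgb2 and Itgal by -3.00 and -2.73.

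Part of the erythroid genes rose in the samples labelled KO. Of 28 measured erythroid genes, 6 rose, 0 fell and 22 did not pass over all genes, and 11 rose adjusted over the list alone (median 1.17, camera adjusted p = 3.12e-06, and adjusted p = 0.656 with an estimated correlation). Gata1, the master regulator of erythroid and megakaryocytic differentiation, rose 7.38-fold, from 6.16 ± 0.60 to 9.04 ± 0.30 (SD, n = 3; limma adjusted p = 0.0109). Icam4, an adhesion molecule of red cell precursors, rose by 2.11 and Add2, a membrane skeleton protein, by 1.50. Besides Car1, the water channel gene Aqp1 and the transcription factor gene Tal1, both named after their values were seen, rose by 3.93 and 3.26. Klf1, the activator of globin genes, differed by 1.91 with an adjusted p of 0.076. Of 18 heme synthesis and iron genes, 1 rose over all genes and 2 adjusted over the list alone (median 0.44, camera adjusted p = 0.0398, and adjusted p = 0.656 with an estimated correlation). It was Tmem14c, a mitochondrial transporter needed for heme synthesis, with 1.23, while Glrx5 differed by 1.98 and passed adjusted over the list alone, and Abcb10 and Fech differed by 1.28 and 1.50 without passing in either adjustment. The heme call was lost without KO replicate 1 or 2 or wildtype replicate 1 or 3 (adjusted p up to 0.419). The mean of the erythroid list was 8.43, 8.16 and 6.63 in KO replicates 1, 2 and 3 and 6.08, 7.35 and 5.65 in wildtype replicates 1, 2 and 3, so wildtype replicate 2 lay above KO replicate 3.

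Megakaryocyte and platelet genes did not move together. Of 26 such genes 1 rose and 1 fell, also adjusted over the list alone (median 0.26, camera adjusted p = 0.906). Itga2b, the platelet integrin gene that is also used as an early haematopoietic marker, rose by 1.76 (limma adjusted p = 0.0232), and the transcription factor gene Fli1 fell by 1.77 (adjusted p = 0.028). Pf4, platelet factor 4, averaged 8.53 ± 3.29 against 7.15 ± 1.37 (SD, n = 3; adjusted p = 0.715).

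Stem and progenitor genes and Hox genes stood slightly higher as lists in the samples labelled KO. Of 27 stem and progenitor genes, 1 rose over all genes, Mllt3, and 5 adjusted over the list alone (median 0.30, camera adjusted p = 0.0247, and adjusted p = 0.585 with an estimated correlation). Bcl11a, Slamf1 and Cdk6 differed by 2.13, 1.05 and 1.43 with limma adjusted p of 0.0518, 0.0526 and 0.0526. Kit, Cd34 and Meis1, markers of immature cells, differed by -0.22, -1.74 and 0.69, with adjusted p of 0.841, 0.376 and 0.344. Of 22 Hox cluster genes and cofactors, 1 rose over all genes and 2 adjusted over the list alone (median 0.33, camera adjusted p = 0.0389, and adjusted p = 0.585 with an estimated correlation). Hoxa10 rose by 1.75 (limma adjusted p = 0.0283), a lower bound since it averaged 3.55 in wildtype, near the floor. Hoxb3 differed by 0.60 and passed adjusted over the list alone, and Hoxa9 and Hoxb5 differed by 2.28 and 0.67 without passing in either adjustment. Hoxb5 averaged 3.41 in wildtype, near the floor, which may compress its difference. The stem and progenitor call was lost without KO replicate 2 or wildtype replicate 2 or 3 (adjusted p up to 0.17), and the Hox call without KO replicate 1 or wildtype replicate 2 (adjusted p up to 0.189).

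**Figure D2:**
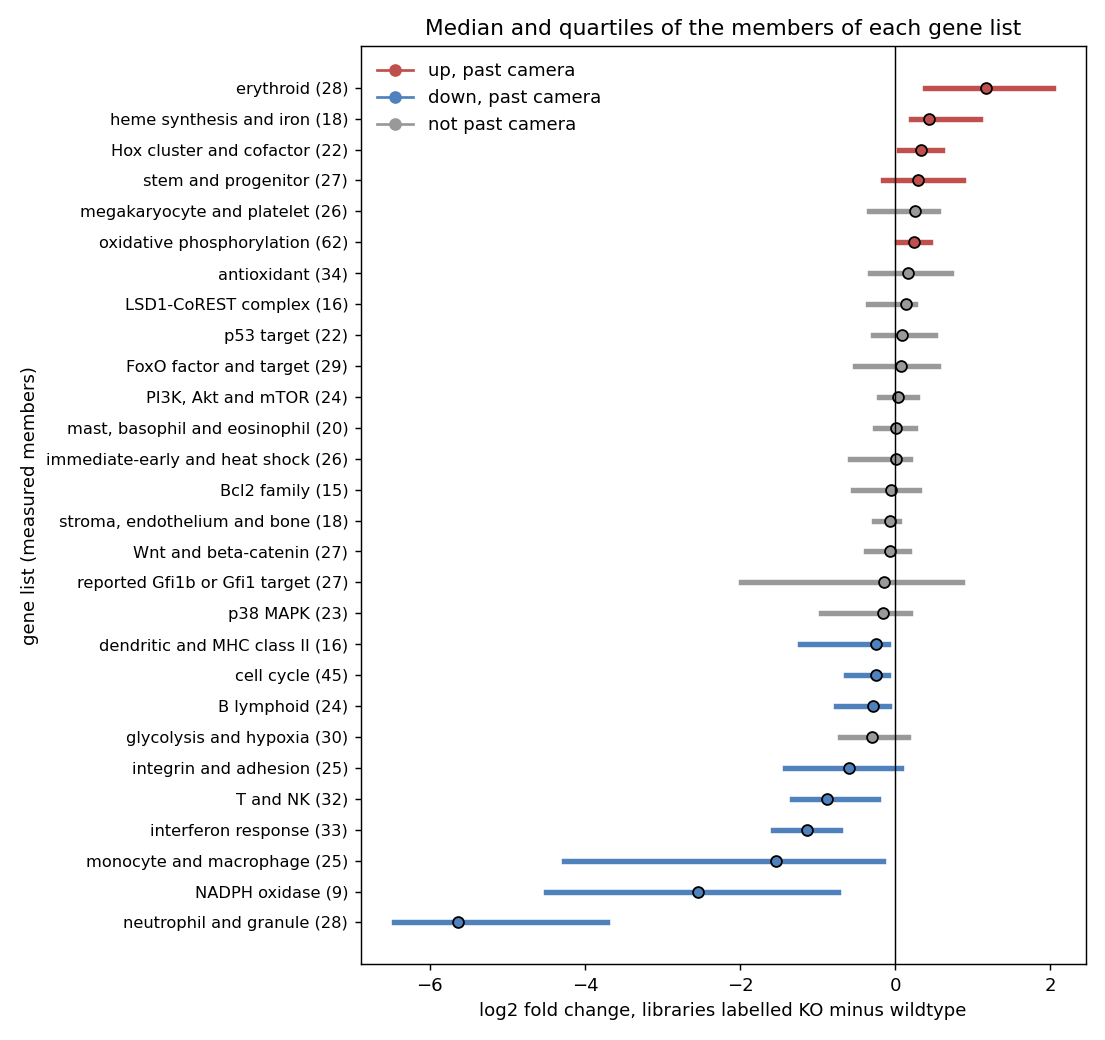
Median (points) and quartiles (bars) of the log2 fold change of the members of 28 gene lists, samples labelled KO minus wildtype, with the number of measured members in brackets and colours for camera's call at the preset correlation. The neutrophil list lies lowest with a median of -5.64 and the erythroid list highest with 1.17, and 0 lists pass with an estimated correlation.

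Lymphoid, antigen presentation and interferon genes were lower as lists in the samples labelled KO, while wildtype replicate 2 stood apart in the T and NK list and wildtype replicate 1 in the MHC class II and interferon lists. Of 24 B lymphoid genes, 2 fell, also adjusted over the list alone, and 22 did not pass (median -0.28, camera adjusted p = 0.0026, and adjusted p = 0.392 with an estimated correlation). They were the immunoglobulin heavy chain gene Ighm, with -3.55, and the B cell receptor gene Cd79b, with -1.83. Spib differed by -0.91 without passing, with a mean of 3.49 in the samples labelled KO, near the floor, which may compress the difference. Of the further probe sets of Ighm, the brightest changed by -4.36 (limma adjusted p over probe sets = 0.00577), and the others, near the floor, differed by -0.58 to 0.07 without passing. The B cell genes Pax5, Ebf1, Ms4a1 and Vpreb1, named after their values were seen, had group means between 3.20 and 3.74, near the floor, and cannot show a difference. Rag1, Rag2 and Dntt, also in this list and named after their values were seen, read highest in wildtype replicate 2. Of 32 T and NK genes, 0 passed over all genes or adjusted over the list alone (median -0.88, camera adjusted p = 0.0026, and adjusted p = 0.656 with an estimated correlation). The list mean was 6.30 in wildtype replicate 2 and between 4.08 and 4.53 in the other 5 samples, and without that replicate the mean log2 fold change went from -0.84 to -0.23 and the list did not pass (adjusted p = 0.101). Ccl5, Zap70, Thy1 and Cd4 differed by -1.25, -0.34, -1.94 and -1.03. Of 16 dendritic cell and MHC class II genes, 0 passed in either adjustment (median -0.24, camera adjusted p = 0.0273, and adjusted p = 0.656 with an estimated correlation). Cd74, the invariant chain, differed by -3.95, and H2-Aa, H2-Eb1 and H2-DMa by -2.97, -2.86 and -2.07. The list mean was 6.33 in wildtype replicate 1 and between 4.61 and 5.14 in the other 5 samples. The call was lost without KO replicate 1 (adjusted p = 0.0801), and without wildtype replicate 1 (adjusted p = 0.102) the mean log2 fold change went from -0.77 to -0.33. Of 33 interferon response genes, 2 fell over all genes and 7 adjusted over the list alone (median -1.14, camera adjusted p = 3.42e-08, and adjusted p = 0.656 with an estimated correlation). Ifi27 fell by 1.34, while Dhx58 and Ddx58 differed by -1.83 and -1.09. Dhx58 averaged 3.53 in the samples labelled KO, near the floor, which may compress its difference. The mean of the interferon list was 6.78 in wildtype replicate 1, 4.85 and 5.13 in wildtype replicates 2 and 3, and between 4.35 and 4.45 in the samples labelled KO. Without wildtype replicate 1 the mean log2 fold change of this list went from -1.19 to -0.59.

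**Figure D3:**
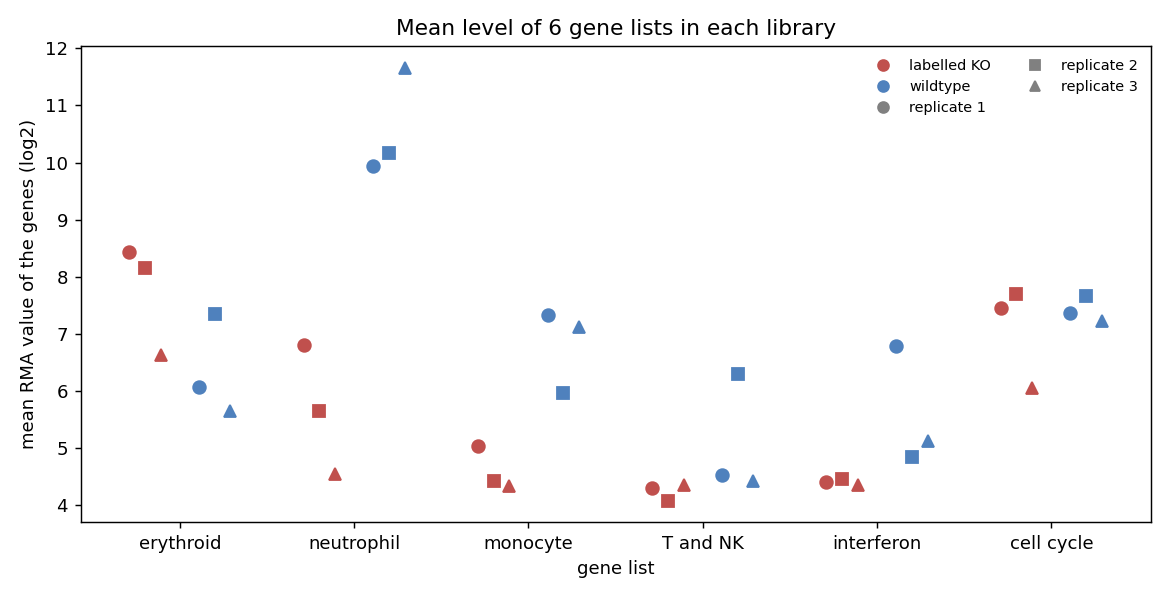
Mean RMA value on the log2 scale of the members of 6 gene lists in each of the 3 samples labelled KO (red) and 3 wildtype samples (blue), with symbols for the replicates. The neutrophil, monocyte, T and NK and interferon lists separate the groups. The T and NK list stands out in wildtype replicate 2 (6.30), the interferon list in wildtype replicate 1 (6.78) and the cell cycle list in KO replicate 3 (6.05).

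Markers of other marrow cells did not pass as lists. Of 20 mast cell, basophil and eosinophil genes, 0 passed over all genes and 2 rose adjusted over the list alone (median 0.02, camera adjusted p = 0.958). These were the transcription factor gene Gata2, with 2.48, and the interleukin-33 receptor gene Il1rl1, with 2.42. Of 18 genes of stroma, endothelium and bone, 1 rose, also adjusted over the list alone (median -0.06, mean 0.05, camera adjusted p = 0.928). It was the collagen gene Col1a2, with 1.75, and the receptor gene Pdgfrb differed by 1.52 (limma adjusted p = 0.0834) at the probe set that represents it and rose by 3.73 (adjusted p over probe sets = 0.0339) at its other probe set, a lower bound since that probe set averaged 3.30 in wildtype, near the floor.

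No gene of the respiration or cell cycle list passed by itself, and both lists passed at the preset correlation and not with an estimated one. Of 62 oxidative phosphorylation genes, 0 passed in either adjustment, and their median was 0.24 (camera adjusted p = 0.0011, and adjusted p = 0.656 with an estimated correlation). Uqcr10, Uqcrc2, Ndufa4 and Ndufa10, subunits of respiratory complexes III and I, differed by 0.49, 0.81, 0.54 and 0.87. Without wildtype replicate 3 the mean log2 fold change went from 0.24 to 0.10 and this list did not pass (adjusted p = 0.0928). Of 45 cell cycle genes, 0 passed in either adjustment, and their median was -0.25 (camera adjusted p = 0.0194, and adjusted p = 0.853 with an estimated correlation). Top2a, Bub1b, Ccne2 and Gins2 differed by -1.11, -1.09, -0.71 and -0.67. The mean of the cell cycle list was 6.05 in KO replicate 3 and between 7.23 and 7.69 in the other 5 samples. Without KO replicate 3 the list turned upwards, with a mean log2 fold change of 0.16 (camera adjusted p = 0.0183), and without wildtype replicate 2 it did not pass (adjusted p = 0.248).

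Genes of redox control moved in both directions. Of 34 antioxidant genes, 3 rose and 3 fell over all genes, and 6 rose and 5 fell adjusted over the list alone (median 0.16, mean -0.0042, camera adjusted p = 0.22). Besides Nfe2l2, the peroxiredoxin gene Prdx6 rose by 2.44 (limma adjusted p = 0.00605). The other members past the threshold, named after their values were seen, were the glutathione synthesis gene Gclm with 1.64, and Prdx5, the glutathione reductase gene Gsr and the glutathione transferase gene Mgst1 with -3.29, -3.04 and -4.92. Without KO replicate 3 the antioxidant list passed upwards (camera adjusted p = 0.0199).

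The signalling and survival lists did not pass camera with all 6 samples. Of 29 FoxO factors and targets, 1 fell over all genes, and 2 rose and 3 fell adjusted over the list alone (median 0.08, mean -0.12, camera adjusted p = 0.795). The interleukin-7 receptor gene Il7r differed by -0.86, with a mean of 3.44 in the samples labelled KO, near the floor, which may compress the difference. Foxo1, Foxo3 and Foxo4 differed by -0.60, -0.24 and -0.16, with limma adjusted p of 0.281, 0.494 and 0.851. Of 24 genes of PI3K, Akt and mTOR signalling, 1 rose and 1 fell, also adjusted over the list alone (median 0.04, mean -0.05, camera adjusted p = 0.958). The translation repressor gene Eif4ebp1 rose by 1.27 and the regulatory subunit gene Pik3r5 fell by 2.30. Of 23 p38 MAPK genes, 1 rose and 2 fell over all genes, and 3 rose and 6 fell adjusted over the list alone (median -0.16, camera adjusted p = 0.142). The phosphatase gene Dusp16 rose by 2.43, the phosphatase gene Dusp1 fell by 2.98, and the kinase gene Mapkapk2, named after its value was seen, fell by 1.57. Without wildtype replicate 2 the p38 list passed downwards (camera adjusted p = 0.0279). Of 27 Wnt and beta-catenin genes, 1 rose, the corepressor gene Tle1 with 1.03, and 0 passed adjusted over the list alone (median -0.07, camera adjusted p = 0.795). The call of Tle1 was lost whichever sample was left out (adjusted p from 0.0536 to 0.131). Pygo2 differed by -0.82. Of 15 Bcl2 family genes, 0 passed in either adjustment (median -0.05, camera adjusted p = 0.394), and Bid and Bmf differed by -0.77 and -0.71.

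Stress lists did not pass either. Of 22 p53 targets, 1 rose, the nuclease gene Aen with 1.27, and 1 fell, the antiproliferative gene Btg2 with -1.95, with 1 and 2 adjusted over the list alone (median 0.09, camera adjusted p = 0.656). Of 26 immediate-early and heat shock genes, taken as signs of handling, 1 rose and 3 fell over all genes, and 2 rose and 4 fell adjusted over the list alone (median 0.0037, mean -0.22, camera adjusted p = 0.26). Btg2, Dusp1 and Fos fell, Fos by 1.77, and the chaperone gene Hspe1 rose by 1.74, Fos and Hspe1 being named after their values were seen. Of 30 glycolysis and hypoxia genes, 2 rose and 2 fell over all genes, and 4 rose and 6 fell adjusted over the list alone (median -0.30, camera adjusted p = 0.102). The hexokinase gene Hk1 rose by 1.28 and the prolyl hydroxylase gene Egln3 fell by 1.51, to a mean of 3.87 near the floor, and Bnip3l and P4ha1, named after their values were seen, changed by 0.84 and -1.26. Without KO replicate 3 this list passed downwards (camera adjusted p = 0.00902).

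Genes reported as Gfi1b or Gfi1 targets went both ways. Of 27 such genes, 2 rose and 7 fell over all genes, and 5 rose and 7 fell adjusted over the list alone (median -0.14, camera adjusted p = 0.427). The TGF-beta receptor gene Tgfbr3 rose 7.65-fold, from 4.11 ± 0.30 to 7.05 ± 0.42 (SD, n = 3; limma adjusted p = 0.00605), and Gfi1b was the other gene that rose. Among the 7 that fell were Csf1r, as given above, and Cebpa with -2.76, Cebpb with -3.43 and the neutrophil elastase gene Ela2 with -5.58, these 3 being named after their values were seen. Of 16 genes of the LSD1-CoREST complex, through which Gfi1b represses, 1 rose, also adjusted over the list alone (median 0.14, mean -0.01, camera adjusted p = 0.958). It was Gse1, with 1.60. Ctbp2 differed by -1.48, with a mean of 3.61 in the samples labelled KO, near the floor, which may compress the difference.

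In all, 14 of the 28 lists passed camera at the preset correlation, 5 higher and 9 lower, and 7 kept the call whichever single sample was left out: the erythroid, neutrophil, monocyte, B lymphoid, NADPH oxidase, interferon and integrin lists. With an estimated correlation 0 passed, and with fry, which does not compare a list with other genes, 3 passed, the neutrophil (adjusted p = 0.031), B lymphoid and NADPH oxidase lists (adjusted p = 0.0247 each), all lower. Of the named genes, Aen, Fli1, Itgal and Tmem14c kept their call in only 1 of the 6 fits without 1 sample. Other splits of the same 6 samples also passed up to 15 lists at the preset correlation. Of the sex-linked genes, the Y-linked Eif2s3y and Ddx3y read 6.70 and 6.07 in KO replicate 2 and at most 3.40 in the other 5 samples, where Xist, expressed from the inactive X chromosome, read between 8.86 and 10.70, against 5.51 in KO replicate 2. Uty and Kdm5d, at the probe sets that represent them, read 3.17 and 3.35 in KO replicate 2, near the floor as in the other samples, and do not show this signal. They differed by -0.05 and 0.03 between the groups. By Xist, Eif2s3y and Ddx3y, KO replicate 2 reads as male and the other 5 samples as female, so the samples labelled KO did not all come from the same mouse. KO replicate 2 is also the sample without which 47 genes passed, and a part of sex in this was not tested.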

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

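Some probe sets outside the gene comparison differed between the groups in the limma fit over all probe sets. Of 5956 probe sets with no gene symbol, 10 were higher and 6 lower in the samples labelled KO at an adjusted p under 0.05. Of 1796 probe sets naming several genes, 39 were higher and 25 lower. That is 0.269% and 3.56% of them, against 3.32% of the probe sets naming 1 gene. The largest differences among them were those of the probe set shared by Chi3l3 and Chi3l4, chitinase-like genes of myeloid cells, with -6.55, and of the probe set shared by the stefin genes Stfa1, Stfa3 and BC100530, with -6.25. The probe set shared by Clca1 and Clca2 was higher by 5.74. These genes were named after their values were seen.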

How the results depend on the processing

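Of the named genes and lists, 1784 gene values and 449 list values across the settings kept their side of the threshold. Those past it in the main fit also kept their direction, while a change of sign among values past it in neither fit was counted as kept. Another 224 and 49 lost the call, 69 and 4 gained it, and 1 and 1 that had passed turned. Nfe2l2 turned to -1.16 after a repeated quantile normalization, because another probe set then represented it, and the mean of the cell cycle list, between -0.67 and 0.16 without 1 sample, turned to 0.16 without KO replicate 3. The count of 933 genes was 1778 at an adjusted p under 0.1, and 0 without variance moderation (limma's linear model alone) and by the authors' ANOVA (3178 genes at an unadjusted p under 0.05 in each). Leaving out 1 sample gave between 47 (KO replicate 2) and 1445 genes (wildtype replicate 2), with 395, 440, 349 and 467 without KO replicate 1, KO replicate 3, wildtype replicate 1 and wildtype replicate 3. The share of higher genes was 48.6%, and 70.2%, 60.2% and 33.6% without KO replicate 2, KO replicate 3 and wildtype replicate 2. The cause of these shifts was not tested beyond the smaller number of samples. The Gfi1b change lay between 5.29 and 6.29 without 1 sample, and was 5.74 with an adjusted p of 0.0584 without KO replicate 2. The 14 lists became 0 with an estimated correlation, 3 with fry, and between 11 and 16 without 1 sample. A replicate block gave 589 genes, 501 of them shared with the 933. Deviations of same-numbered samples correlated by -0.14, -0.00012 and -0.015, which gives no sign that the numbers pair the samples. With 3 samples in a group, single outlying samples weigh heavily on these values, so a pairing is not excluded. The other alternatives stayed within 1.5 times of the counts, apart from the fits with RNA control signals as covariates, which are given below. Signal near the floor limits what can be seen of dim genes.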

Other observations

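The tests on thymocyte genes and the neutrophil list in wildtype replicate 2, the fits with RNA control signals as covariates, and the checks of labels and other splits were chosen only after the results were seen, while the tests of the erythroid spread, the Gfi1b interval and the RNA control probe sets were chosen before. The globin probe sets did not pass the limma test. The probe set shared by the adult beta globin genes Hbb-b1 and Hbb-b2 read 14.40, 14.08 and 11.82 in KO replicates 1, 2 and 3 and 13.20, 14.29 and 13.10 in wildtype replicates 1, 2 and 3. The embryonic beta-like globin gene Hbb-y read between 6.55 and 13.49 in wildtype and between 3.13 and 4.26 in the samples labelled KO at 1 of its probe sets, a difference of -5.88 that did not pass (limma adjusted p over probe sets = 0.122).

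Both counts were set against the 10 splits of the 6 samples into 3 and 3, which are too few for a share under 0.05. The real split gave 933 genes and the highest of the others 0, so 1 split reached the count. Each of the other splits mixes the groups on both sides, so a large group difference widens the spread within sides and lowers the gene count. The count of 0 is therefore no support for the 933. The real split gave 14 lists past camera at the preset correlation and the highest of the others 15, so 2 splits reached the count. The split with 15 sets KO replicates 1 and 2 and wildtype replicate 1 against the rest.

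The first pattern is that Gfi1b is higher in the samples labelled KO. An exchange of labels between single samples of the groups is argued against, since 0 of the 6 samples lay inside the range of the other group for Gfi1b or on the first principal component. An exchange of the labels of both whole groups stays open, because the difference of 5.86 is what it would give and no other measurement here identifies the genotype. The array names in the second deposited table also carry ko or wt, with the same group means. An exchange would therefore have to precede that naming. More cells of the erythroid lineage could also raise Gfi1b. The lower 95% limit of its change, 4.62, lies below the highest upper limit among the erythroid genes, 7.69, so this cannot be excluded. That upper limit is the one of Car1, which rose by 5.48, while the median of the erythroid list was 1.17. A limit set by 1 strongly raised gene could hardly have excluded this explanation, so the test does not decide it. A loss of repression of the locus by its own product, with a transcript still read outside the deleted exons, cannot be told apart with 1 probe set.

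The second pattern is the fall of neutrophil genes with a rise of part of the erythroid genes. A lower share of myeloid cells alone would raise erythroid genes alike if they were expressed in erythroid cells only, which was not checked. Among 21 erythroid genes with a mean of at least 6, changes ran from -0.23 to 5.48. The 95% intervals of 5 excluded their median of 1.56 (exact binomial test against 5%, one-sided, p = 0.00324). Correlated genes make this p too small (estimated correlation of the erythroid list 0.70), so a lower share of myeloid cells alone is not excluded. A difference in RNA degradation as the whole cause of the neutrophil fall is argued against only by the fit with the actin signal, in which the groups overlap. The difference in the mean of the neutrophil list was -4.92 (95% interval -7.27 to -2.57), and in a linear model with the 3' minus 5' signal of the Gapdh or actin controls as covariate it was -3.68 (-6.01 to -1.34) or -3.82 (-5.05 to -2.59), while the changes of all genes moved by a median of 0.13 or 0.096. In limma over all genes 83 or 265 genes then passed, against 933, and of the neutrophil genes 1 or 12, against 21. The Gapdh signal separated the groups, so the fit with it cannot part degradation from the group difference. The slope of the neutrophil mean on the actin signal was -9.49 (95% interval -15.49 to -3.48), so this mean followed the signal. The slope on the Gapdh signal was -8.17 (-18.36 to 2.03). The neutrophil changes were smaller and 3 residual degrees of freedom were left, 1 fewer, so a part of the fall stays open to degradation. For the erythroid genes degradation stays open. The Gapdh signal was higher by 0.15 in the samples labelled KO, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. That of actin was higher by 0.12 with overlapping groups. The Gapdh signal was 0.28 in KO replicate 3, against 0.039 and 0.043 in KO replicates 1 and 2 and at most 0.0086 in wildtype. KO replicate 3 had the lowest erythroid mean of its group, 6.63. Within wildtype, replicate 2 had the highest Gapdh signal and the highest erythroid mean, 7.35. The order within the groups thus does not decide it. A difference in the erythroid cells themselves between the genotypes was not tested.

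The third pattern is T lymphoid genes in wildtype replicate 2 alone, where Cd3d and Tcf7, named after their values were seen, read 9.94 and 9.84, against at most 5.20 and 4.88 in the other 5 samples. Mature T cells of blood alone are argued against, because Rag1, Ptcra, Dntt and Rag2, genes of immature thymocytes, exceeded the higher of the other wildtype samples by 6.46, 5.06, 2.98 and 1.25. A thymus or other lymphoid sample in place of the marrow is argued against, because the mean of the neutrophil list was 10.17, between the 9.94 and 11.66 of the other wildtype samples. Cells of the T lineage, from this leukaemia or from the thymus, may be present: the median excess of the 4 genes was 4.02, and these origins cannot be told apart here. Without this sample 1445 genes passed, against 933.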
